A study of Rattus norvegicus with 12 samples.

How the data were processed

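RNA from 12 cultures of neonatal rat ventricular cardiomyocytes (Sprague Dawley) was measured on 12 whole-transcript expression arrays, 4 from untreated cultures (control), 4 from cultures given the alpha-1 adrenergic agonist phenylephrine (PE) and 4 from cultures given insulin-like growth factor 1 (IGF1). Per the labels, the cells came from 12 rats 1 to 3 days old and 500 ng of RNA was labelled per array. All cultures were moved from serum to serum-free medium before stimulation, and each agent was given at a single dose. The labels do not say which rats went into which culture, so spread between arrays holds both biological and technical differences.

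The deposited intensity values were made by the authors, who name RMA (background correction, normalization between arrays and summary per probe set) without a version. The deposited values were linear, from 2.97 to 14328, not on the log2 scale that RMA usually returns, and the medians of the 12 arrays lay between 38.31 and 40.36. The test had been planned on log2 values, so log2(intensity + 1) was taken first, which had also been planned for linear values. No raw probe signals were used here, and signal over background can only be judged from these summarized intensities. The number of arrays, 4 per group, limits the precision of each value.

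Of 29214 probe sets, 18644 carried 1 gene symbol in the platform's annotation, 962 carried several and 9608 carried none. For the 879 genes with more than 1 probe set the brightest over all arrays was used, which gave 17245 genes. Of the gene IDs, 99% were found in the reference gene table. The annotation names no genome build, so no positions are given.

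Differences were fitted with limma 3.58.1 in R 4.3.3, with all 12 arrays and the group as the only term, which left 9 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over all genes, with a threshold of 0.05 and no fold limit. The 3 comparisons were PE against control, IGF1 against control and PE against IGF1. All tests were two-sided. The array numbers in the sample titles run in 4 consecutive triplets, each with 1 control, 1 PE and 1 IGF1 array. After subtraction of the group means, arrays of different groups in 1 triplet correlated with r from 0.387 to 0.769 (across genes, which are not independent replicates) and arrays of different groups and triplets with r from -0.675 to 0.341. Among arrays of the other groups, all 12 correlated best with 1 of their own triplet. A second fit with the triplet as a block, with 6 residual degrees of freedom, was therefore decided on before its calls were compared, and is called the paired test. The log2 differences are the same in both. The titles also give a well column, 05 for 8 arrays and 07 for Control replicate 2, PE replicate 2 and IGF1 replicates 1 and 3.

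Gene lists written from textbook knowledge before the data were examined, 35 for pathways and 9 for cell types, were tested where at least 5 members were measured. Each was described by its members past the threshold over all genes and adjusted over the list alone, by its median log2 difference, and by limma's camera with a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists of each kind. An estimated correlation was the alternative, and fry was run beside it.

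The rule for naming genes was also written before the data were examined. For each agent against control it names the 10 largest rises and the 10 largest falls among genes past the threshold whose 4 treated arrays all lay on 1 side of the 4 control arrays. It also names Kif5b, Kif5a, Kif5c, Klc1, Nppa, Nppb, Acta1, Myh6, Myh7, Atp2a2 and Rcan1, and up to 4 members of each list described, or 2 where none passed. For PE against IGF1 it names 5 in each direction and up to 2 per list, and for both agents 5 per direction. Placeholder symbols were counted and not named. Areg, Nt5e, Cpt1a, Cpt1b, Acsl1, Ppara, Scn4b, Kcnj3, Kcnj2, Gja1, Elovl6, Psmd3 and Klf5, and in PE against IGF1 also Il1rl1, Pdlim5, Furin, Adra1a, Igf1r, Klhl24 and Insr, were named after their values were seen.

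The procedure was tested on simulated data with 17245 genes modelled on PE against control. Of 100 genes shifted by 0.5 on the log2 scale it recovered 50, and of 100 shifted by 1 it recovered 94, with 1 false call. The paired test recovered 78 and 100, with 7 false calls. A sarcomere list shifted by 0.3 was called by camera with the triplet as a block, and 0 of the lists that share no gene with it were called. Each simulated gene varied on its own around the triplet means. This therefore does not test camera on genes that vary together, nor camera in the unpaired fit.

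Alternatives tried were centring each array on its median, quantile normalization, leaving out the dimmest genes (those below the 33.3% quantile of the mean level), the mean over a gene's probe sets, a mean-variance trend with robust priors, array weights, fitting only the 2 groups compared, a fold limit of 1.5, an adjusted p threshold of 0.01, the triplet or the well column as a block, and well column 05 alone. Each array was also left out in turn. Log2 with no pseudocount, leaving out arrays 1 to 3, well column 07 alone, and every alternative to the paired test were added after the data were seen.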

Results

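Expression was measured in 12 cultures of neonatal rat heart muscle cells, 4 per group, to compare gene activity after the hypertrophic stimuli PE and IGF1 with that of untreated cells. The series title concerns KIF5B, a heavy chain of the motor protein kinesin-1, and the placement of mitochondria. Median intensity lay between 38.31 and 40.36 in every array, and any pair of arrays correlated across genes with r of at least 0.9862. The triplets of consecutive array numbers held 50.7% of the variance, the treatment groups 32.1% and the well columns 11.9%. A factor with more levels takes up more variance by chance, and the columns overlap with the triplets. These shares therefore neither add up nor compare directly. The first principal component (36.9% of variance) set arrays 1 to 3 apart from the rest, which is why the paired test is given beside the unpaired test.

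**Figure D1:**
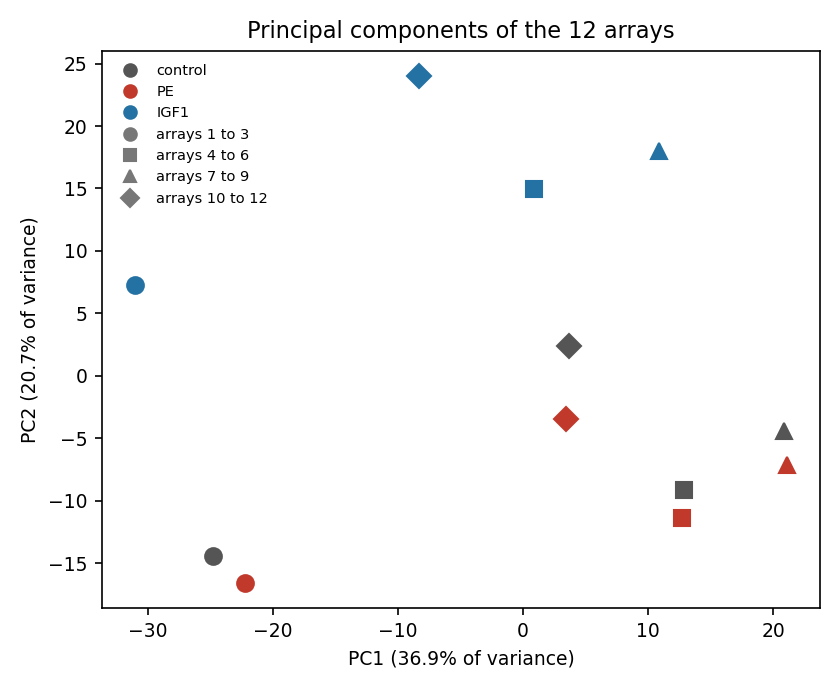
Principal components of the 12 arrays over all 17245 genes, with PC1 (36.9% of variance) on the x axis and PC2 (20.7%) on the y axis. Colours give the group and shapes the triplet of array numbers. Arrays 1 to 3 lie at the low end of PC1, and the IGF1 arrays lie above the other arrays on PC2.

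PE against control asks what alpha-1 adrenergic stimulation changes. Kif5b rose 1.59-fold with PE, from 2164 ± 93.3 in controls to 3457 ± 471 (intensity, mean ± SD, n = 4 arrays each), and it was higher in 4 of 4 triplets. Across 17245 genes, 82 rose and 18 fell. Among the genes that rose with the groups fully apart, the largest changes were in Wfdc1, a secreted protease inhibitor-like protein (4.07-fold, 858.5 ± 242 against 213.5 ± 77.6), Bdkrb2, the bradykinin B2 receptor (3.48-fold), Rln3, the relaxin 3 gene (3.02-fold), and Otud1, a deubiquitinase (2.95-fold). The others were Cavin4, a muscle caveola protein (2.82-fold), F2rl1, a protease-activated receptor (2.79-fold), Inha, the inhibin alpha subunit (2.66-fold), Grtp1 (2.61-fold), Pnoc, the nociceptin precursor (2.53-fold), and Dusp8, a phosphatase of stress kinases (2.48-fold). Their adjusted p ran from 0.00415 for Bdkrb2 to 0.0488 for F2rl1 and Grtp1. Because they were picked with the groups fully apart, each was by construction higher in 4 of 4 triplets. Rln3 and Pnoc were dim in controls, at 15.2 ± 1.67 and 23.9 ± 3.05.

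The largest falls with PE were in Gbp1, an interferon-induced GTPase (2.17-fold lower), Aldoc, an aldolase of glycolysis (1.96-fold lower), the membrane glycoprotein gene Gpm6a (1.86-fold lower) and the glutamate receptor gene Gria1 (1.84-fold lower). The kinase gene Hunk was 1.80-fold lower, the actin-associated Fam107a 1.69-fold lower, Gamt, of creatine synthesis, 1.64-fold lower, Pkd1l1 1.64-fold lower, and the lipoprotein lipase gene Lpl 1.56-fold lower. The sulfotransferase gene Chst9 was lower too, at 10.9 ± 0.97 against 17.0 ± 2.62, but with PE it lay at the lower quartile of the arrays (10.73 to 11.49), so the size of its fall is uncertain. Adjusted p ran from 0.00192 for Pkd1l1, at 49.4 ± 0.367 against 81.5 ± 2.91, to 0.0488 for Aldoc, Fam107a and Chst9. These too were picked with the groups fully apart, so each was by construction lower in 4 of 4 triplets.

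Kif5b (probe set 10795548) had a log2 difference of 0.67 with PE (SE 0.097, adjusted p = 0.0143). The paired test gave SE 0.071 and adjusted p = 0.000508. The unpaired call ended with only the 2 groups compared (adjusted p = 0.0536) and within well column 05 (0.213). It also ended without Control replicate 3 (adjusted p = 0.0588) or without PE replicate 3 (0.0546). An exact permutation test of 4 against 4 arrays gave p = 0.0286, and an exact sign flip over the 4 triplets p = 0.125, each the smallest that its design allows. With IGF1, Kif5b stood at 2592 ± 209, 1.20-fold over control in 4 of 4 triplets, which did not pass the unpaired test (log2 difference 0.26, adjusted p = 0.197) and passed the paired test (adjusted p = 0.0304). That paired call ended when any of 7 single arrays was left out. The difference between PE and IGF1 itself passed (1.33-fold, adjusted p = 0.0381, paired 0.00247). The neuronal heavy chain genes Kif5a and Kif5c and the light chain gene Klc1 did not pass with PE (log2 differences 0.14, -0.04 and -0.02, adjusted p = 0.64, 0.972 and 0.972), nor with IGF1. Kif5a and Kif5c were dim in controls, at 17.0 ± 0.54 and 24.5 ± 4.70, where a change is hard to see. Kif5b was the 1 gene of 29 on the list of kinesins and mitochondrial transport that passed with PE, also when adjusted over the list alone, and in the paired test 1 rose and 1 fell. That list's median was -0.02 while its mean was 0.01 (camera adjusted p = 0.478).

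**Figure D2:**
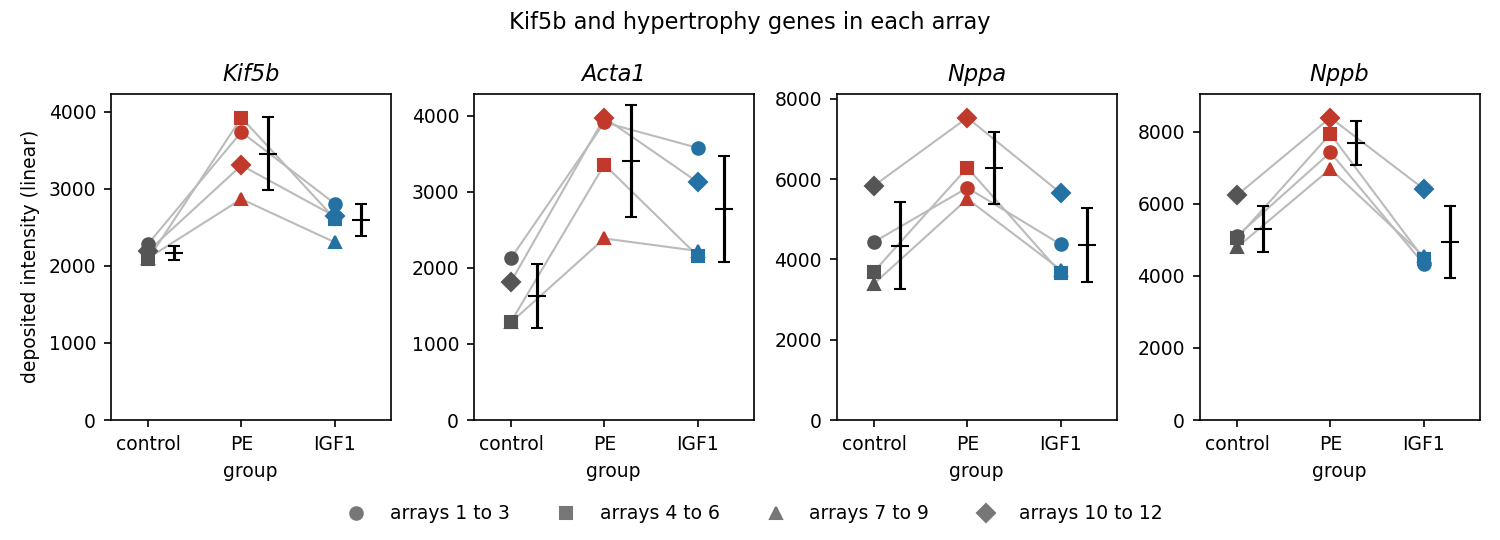
Deposited intensity (linear, y axis from 0) of Kif5b, Acta1, Nppa and Nppb in each array by group, with grey lines joining arrays of 1 triplet and black marks giving mean and SD of 4 arrays. Kif5b averages 3457 with PE, 2592 with IGF1 and 2164 in controls.

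Some markers of hypertrophy rose with PE. Of 20 measured genes that return to their fetal level or rise in cardiac hypertrophy, 3 rose over all genes, 11 adjusted over the list alone and 14 in the paired test. Their median log2 difference was 0.49 (camera adjusted p = 4.22e-13, adjusted p = 0.0562 with an estimated correlation). The 3 were Fhl1, a stretch-sensing LIM protein (2.03-fold), Enah, an actin regulator (1.77-fold), and the protease inhibitor gene Timp1 (1.42-fold). The skeletal actin gene Acta1 (2.10-fold, adjusted p = 0.0564, paired 0.000133), Nppb (1.46-fold, 0.0885, paired 0.00143) and Nppa (1.47-fold, 0.247, paired 0.00195), which encode natriuretic peptides, rose in the paired test only, each in 4 of 4 triplets. Atp2a2, the calcium pump gene, fell in the paired test only (log2 difference -0.27, adjusted p = 0.618, paired 0.0244). The myosin genes Myh6 and Myh7 (log2 differences 0.19 and 0.12) and the calcineurin target Rcan1 (0.23) passed neither test, with adjusted p of 0.953, 0.71 and 0.666. Of 18 adult-type genes that usually fall in hypertrophy, Klf15 fell over all genes, as it did adjusted over the list alone, and 1 rose and 5 fell in the paired test. Their median was -0.09 (camera adjusted p = 0.457, adjusted p = 0.988 with an estimated correlation). Of 26 sarcomere genes, Csrp3 (2.03-fold) and Pdlim5 (2475 ± 207 against 1649 ± 141), which encode Z-disc proteins, rose over all genes, 4 rose adjusted over the list alone and 11 in the paired test. Their median was 0.22 (camera adjusted p = 9.65e-10, adjusted p = 0.467 with an estimated correlation). The 12 cardiomyocyte markers had a median of 0.16 with 0 past the threshold over all genes or adjusted over the list alone (limma, 3 at unadjusted p under 0.05, 3 in the paired test, camera adjusted p = 0.00226, adjusted p = 0.572 with an estimated correlation), and 11 of the 12 also stand on other lists.

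A few signalling genes rose with PE as well. Among 25 immediate early and growth response genes the orphan nuclear receptor gene Nr4a3 (2.28-fold) and Ier5 (1.27-fold) passed, 6 passed adjusted over the list alone and 10 in the paired test. Their median was 0.18 (camera adjusted p = 3.62e-10, adjusted p = 0.163 with an estimated correlation). Among 24 feedback genes of MAP kinase and Gq signalling, Dusp8 and Rgs2, a brake on Gq (2.18-fold), rose, 5 rose and 1 fell adjusted over the list alone, and 6 rose and 1 fell in the paired test. Their median was 0.19 (camera adjusted p = 3.74e-06, adjusted p = 0.0562 with an estimated correlation). Adra1a, an alpha-1 receptor gene (1.64-fold), and Ace, the angiotensin-converting enzyme gene (1.63-fold), were the 2 of 19 natriuretic and vasoactive genes past the threshold, 4 rose adjusted over the list alone, and 4 rose and 5 fell in the paired test. That list's median was -0.07 while its camera direction was up (adjusted p = 0.637). Of 27 YAP, SRF and cytoskeleton genes 0 passed over all genes (limma, 11 higher at unadjusted p under 0.05), 5 adjusted over the list alone and 10 in the paired test, Cnn1 (2.06-fold, paired adjusted p = 0.00156) and Tubb6 (1.46-fold, 0.00115) foremost. Their median was 0.13 (camera adjusted p = 3.19e-07, adjusted p = 0.163 with an estimated correlation). Of 11 smooth muscle and pericyte markers, among them Cnn1, 0 passed over all genes (limma, 4 higher and 1 lower at unadjusted p under 0.05), 3 rose adjusted over the list alone, and 4 rose and 2 fell in the paired test, with a median of 0.03 that was above 0 in 4 of 4 triplets.

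Some metabolic genes rose and others fell with PE. Of 19 cholesterol synthesis genes 6 rose over all genes, 12 adjusted over the list alone and 13 in the paired test, led by Idi1 (1.95-fold), Hsd17b7 (1.65-fold), Sqle (1.48-fold) and Cyp51 (1.47-fold). Their median was 0.39 (camera adjusted p = 6.61e-21, adjusted p = 0.0562 with an estimated correlation). In glycolysis, Eno3, the muscle enolase gene (2.37-fold), and the lactate exporter gene Slc16a3 (2.11-fold) rose while Aldoc fell, 2 up and 1 down of 23 also adjusted over the list alone, and 4 up and 2 down in the paired test. The glycolysis median was -0.03 while its mean was 0.04 (camera adjusted p = 0.415). Of 29 fatty acid oxidation genes 0 passed over all genes (limma, 8 lower at unadjusted p under 0.05), 2 fell adjusted over the list alone and 7 fell in the paired test. Their median was -0.22 (camera adjusted p = 7.67e-06, adjusted p = 0.692 with an estimated correlation). These included Hadh (1.56-fold lower, paired adjusted p = 0.00763), Pdk4, which restrains glucose oxidation (1.66-fold lower, 0.0434), the carnitine palmitoyltransferase genes Cpt1a (1.47-fold lower, 0.0105) and Cpt1b (1.47-fold lower, 0.0145), Acsl1 (1.53-fold lower, 0.0128) and the lipid-sensing receptor gene Ppara (1.36-fold lower, 0.0046). Of 33 genes of respiratory complex I and 42 of complexes II to V 0 passed in either test, adjusted over the list alone or at unadjusted p under 0.05 (limma), with medians of -0.04 and -0.01. Of 19 TCA cycle genes 0 passed in either test or adjusted over the list alone (limma, 2 lower at unadjusted p under 0.05). Of 18 fatty acid synthesis genes 0 passed over all genes or adjusted over the list alone (limma, 2 higher at unadjusted p under 0.05). In the paired test 5 of these rose and 1 fell. Their median was 0.11 (camera adjusted p = 0.0486, adjusted p = 0.733 with an estimated correlation).

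The insulin-repressed regulator gene Klf15 (1.49-fold lower) was the 1 of 31 FoxO target and insulin feedback genes that fell with PE over all genes, and 8 fell and 1 rose adjusted over the list alone, 10 falling in the paired test. Their median was -0.16 (camera adjusted p = 3.11e-05, adjusted p = 0.21 with an estimated correlation). Of 21 interferon response genes 0 passed over all genes or adjusted over the list alone (limma, 3 lower at unadjusted p under 0.05) and 8 fell in the paired test, among them Irf7, a master regulator of interferon genes (2.10-fold lower, paired adjusted p = 0.00355), and Oas1a (2.05-fold lower, 0.0112). The interferon median was -0.38 (camera adjusted p = 0.00136, adjusted p = 0.854 with an estimated correlation), -0.03 in 1 triplet and -0.63 in another, while the 15 leukocyte markers had a median of -0.06. The median of 29 proteasome genes was 0.07 with 0 past the threshold in either test, adjusted over the list alone or at unadjusted p under 0.05 (limma, camera adjusted p = 0.000161, adjusted p = 0.467 with an estimated correlation).

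In the paired test 672 genes rose and 719 fell with PE, among them all 100 of the unpaired test. Groups were fully apart in 958 genes (5.56%, where chance would give 2.86% if all 8 arrays were exchangeable, which leaves the triplets out of account). Leaving out single arrays gave from 11 (without PE replicate 3) to 80 genes higher, and from 3 (without Control replicate 2, Control replicate 3 or PE replicate 2) to 41 (without PE replicate 1) lower. With the well column as a block 125 rose and 52 fell, and within well column 05 0 passed (limma, 613 higher and 528 lower at unadjusted p under 0.05). Column 07 holds 1 control, 1 PE and 2 IGF1 arrays, where a test leaves 1 residual degree of freedom and takes lone arrays to vary like the IGF1 arrays. Its count of 0 (limma, 387 higher and 718 lower at unadjusted p under 0.05) therefore says nothing about the other calls. The hypertrophy list's median was 0.51 in column 05 and 0.43 in column 07.

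IGF1 against control asks what this growth factor changes in the same cells. Among named genes with the groups fully apart, Cenpu, a centromere protein gene, rose most, 2.61-fold from 38.0 ± 11.03 to 100.4 ± 25.7 (intensity, mean ± SD, n = 4 arrays each). Across 17245 genes 371 rose and 205 fell. After Cenpu came the spindle checkpoint kinase gene Bub1b (2.30-fold), the ubiquitin-conjugating enzyme gene Ube2t (2.29-fold), Depdc1 (2.27-fold), the replication factor gene Pclaf (2.27-fold), the cytokinesis gene Cep55 (2.21-fold), the replication kinase gene Cdc7 (2.21-fold), the mitotic DNA translocase gene Ercc6l (2.19-fold), the origin licensing gene Cdc6 (2.19-fold) and Cenpk (2.18-fold). Adjusted p ran from 0.00374 for Cdc7 to 0.039 for Depdc1. With the groups fully apart by the rule that picked them, each was necessarily higher in 4 of 4 triplets.

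The largest falls with IGF1 were in Lrrc2, a mitochondria-associated leucine-rich repeat gene (3.47-fold lower, 82.5 ± 10.5 against 289.7 ± 44.5), Hamp, the gene of the iron hormone hepcidin (3.15-fold lower), Myom2, of the sarcomeric M-band (2.73-fold lower), and Pamr1 (2.64-fold lower). The others were Asb14 (2.35-fold lower), Tcp11l2 (2.32-fold lower), Ypel3 (2.26-fold lower), the interferon-induced chemokine gene Cxcl11 (2.24-fold lower), Pdk4 (2.21-fold lower) and Selplg, a selectin ligand gene (2.14-fold lower). Adjusted p ran from 0.000362 for Pamr1 to 0.0393 for Asb14 and Pdk4. With the groups fully apart by the rule that picked them, each was necessarily lower in 4 of 4 triplets.

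Of 37 mitosis genes 16 rose with IGF1 over all genes, and 36 rose both adjusted over the list alone and in the paired test. Their median log2 difference was 1.00 (camera adjusted p = 1.05e-27, adjusted p = 0.178 with an estimated correlation). Besides Bub1b they included Hmmr (2.17-fold), the kinetochore gene Nuf2 (2.06-fold) and the cytokinesis motor gene Kif23 (2.04-fold). Of 35 genes of DNA replication and the G1/S transition 27 rose, 34 adjusted over the list alone and 35 in the paired test, among them Cdc6, the cyclin gene Ccne2 (2.18-fold), the polymerase gene Pole (2.08-fold) and the helicase gene Mcm5 (304.4 ± 86.0 against 148.9 ± 22.2). Their median was 0.74 (camera adjusted p = 9.26e-41, adjusted p = 0.0554 with an estimated correlation). Of 13 mitotic kinesins 7 rose over all genes and 13 both adjusted over the list alone and in the paired test (median 0.95, camera adjusted p = 6.02e-14, adjusted p = 0.159 with an estimated correlation), Kif23, Kif20b (1.97-fold), Cenpe (1.93-fold) and Kif18b (1.79-fold) foremost. Kif20b and Kif18b were apart from all controls, while Kif23 and Cenpe overlapped with them. The mitosis median was 0.55 in the lowest and 1.18 in the highest of the 4 triplets, and the 13 fibroblast markers, 6 of them on other lists, had a median of 0.05.

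Many cholesterol and some fatty acid synthesis genes rose with IGF1. Of 19 cholesterol synthesis genes 14 rose, and 18 both adjusted over the list alone and in the paired test, with Idi1 (1.96-fold), Acat2 (1.90-fold), Hsd17b7 (1.76-fold) and Mvd (1.62-fold) foremost. Their median was 0.54 (camera adjusted p = 5.02e-21, adjusted p = 0.0554 with an estimated correlation). Of 18 fatty acid synthesis genes 5 rose, namely the desaturase genes Fads1 (1.78-fold) and Scd2 (1.68-fold), the acetyl-CoA enzyme genes Acss2 (1.57-fold) and Acaca (1.46-fold) and the elongase gene Elovl6 (1.45-fold). Adjusted over the list alone 10 rose, and in the paired test 11 rose and 1 fell. Their median was 0.44 (camera adjusted p = 2.32e-06, adjusted p = 0.14 with an estimated correlation). Eno3 (1.87-fold) rose as the 1 of 23 glycolysis genes past the threshold, 2 adjusted over the list alone and 9 in the paired test. Their median was 0.15 (camera adjusted p = 0.000546, adjusted p = 0.26 with an estimated correlation). Of 29 fatty acid oxidation genes 1 fell, both over all genes and adjusted over the list alone, and 5 fell in the paired test. Their median was -0.07 (camera adjusted p = 0.0908, adjusted p = 0.734 with an estimated correlation). It was 0.07 within well column 05 and -0.60 within column 07.

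A few genes of the proteasome and of amino acid supply also rose with IGF1. Of 29 proteasome genes Psmd14 (1.28-fold), Psmc1 (1.26-fold) and Psmd3 (1.18-fold) rose over all genes, 8 adjusted over the list alone and 14 in the paired test. Their median was 0.18 (camera adjusted p = 4.96e-12, adjusted p = 0.0971 with an estimated correlation, paired 0.0367). Of 30 amino acid response genes Gpt2 (1.33-fold) passed over all genes, 2 rose and 1 fell adjusted over the list alone, and 16 rose and 2 fell in the paired test. Their median was 0.23 (camera adjusted p = 0.000419, adjusted p = 0.467 with an estimated correlation). Of 19 tRNA synthetase genes 0 passed over all genes (limma, 8 higher at unadjusted p under 0.05), 6 adjusted over the list alone and 10 in the paired test, with Yars1 foremost (1.37-fold, paired adjusted p = 0.000937, median 0.19, camera adjusted p = 3.67e-06, adjusted p = 0.28 with an estimated correlation).

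Some mitochondrial genes showed small differences with IGF1 in the paired test. Of 19 TCA cycle genes 0 passed over all genes (limma, 2 higher at unadjusted p under 0.05), 1 rose adjusted over the list alone and 6 in the paired test, among them Pdhx (1.40-fold, paired adjusted p = 0.000412) and Ogdh (1.20-fold, 0.00748), with a median of 0.13 (camera adjusted p = 0.000894, adjusted p = 0.589 with an estimated correlation) that was -0.01 within well column 07. Of 33 complex I genes 0 passed over all genes or adjusted over the list alone (limma, 1 higher at unadjusted p under 0.05) and 5 rose in the paired test, including Ndufs1 (1.20-fold, paired adjusted p = 0.00722). Of 42 genes of complexes II to V 0 passed over all genes, adjusted over the list alone or at unadjusted p under 0.05 (limma), and 3 rose in the paired test, including Atp5mc1 (1.24-fold, 0.0057). Medians of the last 2 lists were 0.11 and 0.08 (camera adjusted p = 0.00823 for each, adjusted p = 0.734 with an estimated correlation), and within well column 07 they were -0.05 and -0.07.

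Several FoxO targets and insulin feedback genes fell with IGF1. Of 31, 12 fell and 1 rose over all genes, 21 fell and 1 rose adjusted over the list alone, and 24 fell and 1 rose in the paired test. Their median was -0.32 (camera adjusted p = 3.55e-13, adjusted p = 0.0554 with an estimated correlation). The falls included Pdk4, the atrophy ubiquitin ligase gene Fbxo32 (2.09-fold lower) and Klf15 (1.70-fold lower), while Sesn3, a sestrin gene, rose 1.66-fold. Of 15 IGF axis genes the receptor gene Igf1r fell (1.40-fold lower) and the binding protein gene Igfbp5 rose (1.82-fold), 2 falling and 1 rising adjusted over the list alone, and 5 and 2 in the paired test. Of 27 autophagy and lysosome genes Gabarapl1 (1.45-fold lower) and Map1lc3b (1.23-fold lower), both of the autophagosome membrane, fell over all genes, 6 adjusted over the list alone and 11 in the paired test. Their median was -0.15 (camera adjusted p = 3.01e-05, adjusted p = 0.0653 with an estimated correlation).

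Of 30 inflammation and chemokine genes 0 passed over all genes or adjusted over the list alone with IGF1 (limma, 4 lower at unadjusted p under 0.05) and 18 fell in the paired test, including the chemokine genes Ccl20 (1.87-fold lower, paired adjusted p = 0.000636) and Cxcl1 (1.70-fold lower, 0.00461). Their median was -0.40 (camera adjusted p = 0.00065, adjusted p = 0.602 with an estimated correlation). The 15 leukocyte markers had a median of -0.27, with 0 past the threshold over all genes or adjusted over the list alone (limma, 1 lower at unadjusted p under 0.05). In the paired test 7 fell, among them Cd68 (1.42-fold lower, paired adjusted p = 0.00476) and Fcer1g (1.33-fold lower, 0.0059). Camera gave them adjusted p = 0.138, paired 0.00378, and paired 0.551 with an estimated correlation. The 10 endothelial and 9 epicardial markers had medians of -0.13 and -0.17, below 0 in 4 of 4 triplets. Of each list 0 passed over all genes (limma), and 1 and 3 fell in the paired test. Their camera adjusted p was 0.138 and 0.585, paired 0.0426 for each, and paired 0.551 for each with an estimated correlation. Of 25 immediate early genes Klf5 fell (1.22-fold lower), 2 fell adjusted over the list alone, and 5 fell and 1 rose in the paired test. Their median was -0.18 (camera adjusted p = 0.0293, adjusted p = 0.589 with an estimated correlation). Of 24 MAP kinase and Gq feedback genes 0 passed over all genes (limma, 6 lower at unadjusted p under 0.05), 3 fell adjusted over the list alone and 6 in the paired test, including Rgs16 (1.73-fold lower, 0.000862) and Dusp4 (1.49-fold lower, 0.000813). Their median was -0.13 (camera adjusted p = 0.0158, adjusted p = 0.209 with an estimated correlation).

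Hypertrophy markers did not rise as a group with IGF1. Of 20, 0 passed over all genes or adjusted over the list alone (limma, 1 higher and 2 lower at unadjusted p under 0.05), and 2 rose and 4 fell in the paired test. Their median was -0.03 (camera adjusted p = 0.808). Acta1 rose in the paired test only (1.70-fold, adjusted p = 0.0872, paired 0.000272) and the endothelin gene Edn1 fell in it only (1.79-fold lower, 0.227, paired 2.99e-05). Myh6 was 2.03-fold higher in the paired test only (adjusted p = 0.355, paired 6.74e-05), at 1334 ± 957 against 613.0 ± 325, and higher in 4 of 4 triplets. Nppa, Nppb and Myh7 passed neither test (log2 differences 0.01, -0.11 and -0.07, adjusted p = 0.983, 0.732 and 0.753), nor did Atp2a2 and Rcan1 (-0.12 and -0.07, adjusted p = 0.766 and 0.887). Myom2 was the 1 of 26 sarcomere genes past the threshold, also adjusted over the list alone, while 7 rose and 1 fell in the paired test. The list's median was 0.15 (camera adjusted p = 0.0439, adjusted p = 0.734 with an estimated correlation) and -0.004 within well column 07. Of 18 adult-type genes Klf15 fell, 1 rose and 1 fell adjusted over the list alone, and 5 rose and 2 fell in the paired test. Their median was 0.10 (camera adjusted p = 0.78, adjusted p = 0.919 with an estimated correlation) and -0.185 within well column 07.

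**Figure D3:**
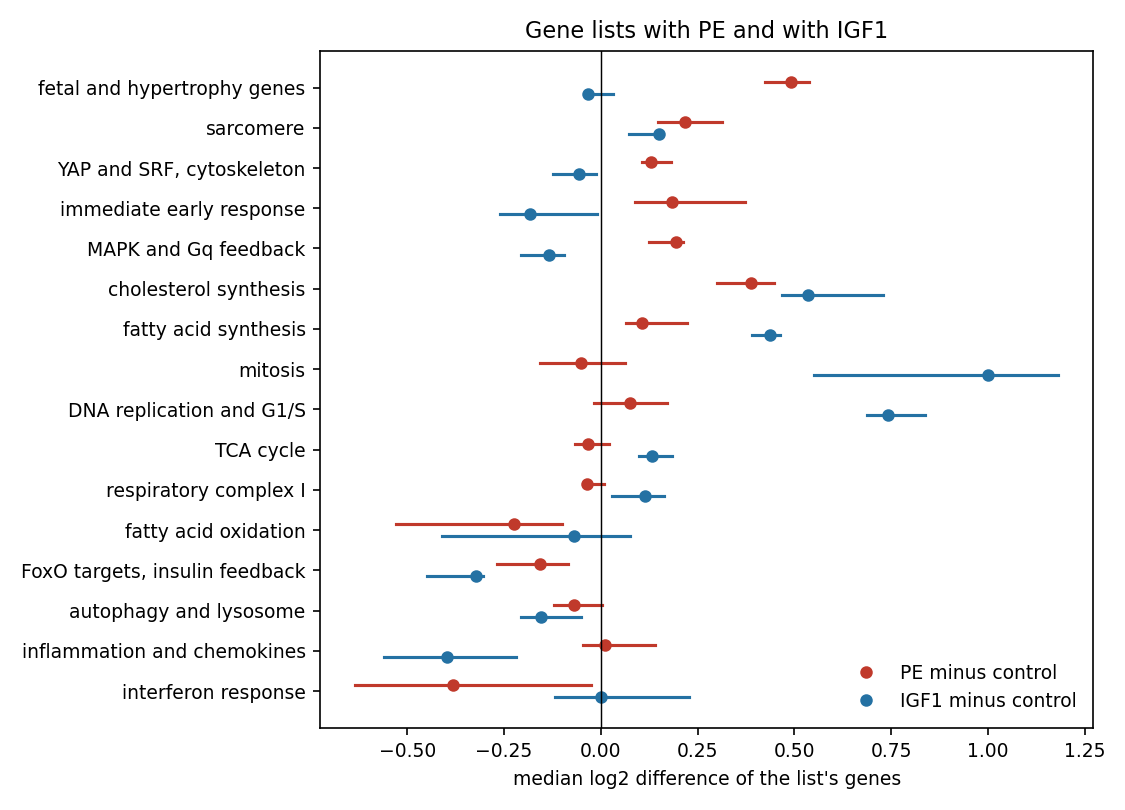
Median log2 difference against control (x axis) of the measured genes of 16 lists (y axis), for PE in red and IGF1 in blue, with lines from the lowest to the highest of the 4 triplets. The mitosis list stands at 1.00 with IGF1 and -0.05 with PE, and the hypertrophy list at 0.49 with PE and -0.03 with IGF1.

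In the paired test 1466 genes rose and 1379 fell with IGF1, among them all 576 of the unpaired test. Groups were fully apart in 1747 genes (10.1%, against the same 2.86% that leaves the triplets out of account). Leaving out single arrays gave from 84 (without Control replicate 3) to 396 genes higher and from 50 (without Control replicate 3) to 201 lower. Within well column 05, with 3 control and 2 IGF1 arrays, 43 rose and 8 fell. Within column 07, with 1 control array, 0 passed (limma, 420 higher and 724 lower at unadjusted p under 0.05), which with 1 residual degree of freedom says nothing about the other calls. The mitosis median was 0.84 and 0.85.

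PE against IGF1 tests directly where the agents differ, at the single dose of each and in cells kept without serum before stimulation. Bdkrb2 was 4.72-fold higher with PE than with IGF1, at 129.7 ± 28.8 against 26.6 ± 5.25 (intensity, mean ± SD, n = 4 arrays each), and Pbk, a mitotic kinase gene, was 2.99-fold lower, at 98.1 ± 36.0 against 311.6 ± 168. Across 17245 genes 284 were higher with PE and 367 lower. Next among the higher ones were Lrrc2 (3.69-fold), Otud1 (3.58-fold), the cytokine receptor gene Csf2rb (3.43-fold) and Wfdc1 (3.40-fold), and among the lower ones Hjv, of iron regulation (2.67-fold lower), the cohesin acetyltransferase gene Esco2 (2.65-fold lower), Igfbp5 (2.64-fold lower) and Pclaf (2.45-fold lower). Adjusted p ran from 0.000455 for Bdkrb2 and Lrrc2 to 0.0382 for Pbk. As these were picked with the groups fully apart, the direction was by construction the same in 4 of 4 triplets.

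Several hypertrophy and signalling genes were higher with PE than with IGF1. Of 20 hypertrophy genes 7 were higher over all genes, 11 adjusted over the list alone, and 17 higher and 1 lower in the paired test, including Hbegf, an EGF receptor ligand gene (2.07-fold), and Ccn2, a matricellular growth factor gene (1.90-fold). Their median was 0.57 (camera adjusted p = 2.09e-10, adjusted p = 0.0853 with an estimated correlation). Nppb was 1.57-fold higher (adjusted p = 0.0145). Of 18 adult-type genes 0 passed over all genes or adjusted over the list alone (limma, 2 lower at unadjusted p under 0.05) and 6 were lower in the paired test. Their median was -0.11 (camera adjusted p = 0.364). Of 24 MAP kinase and Gq feedback genes 8 were higher over all genes, 11 higher and 1 lower adjusted over the list alone, 15 and 2 in the paired test, with Rgs2 (2.12-fold) and Dusp8 (680.9 ± 101 against 342.4 ± 77.5) foremost, and in the unpaired test this was the only list of the 35 pathways and 3 comparisons to pass with both correlations. Their median was 0.33 (camera adjusted p = 5.18e-10, adjusted p = 0.0162 with an estimated correlation), and with that correlation the paired test did not call it (adjusted p = 0.101). Of 25 immediate early genes 7 were higher over all genes, 17 higher and 1 lower both adjusted over the list alone and in the paired test, including Nr4a1 (2.25-fold) and Nr4a3 (2.24-fold). Their median was 0.38 (camera adjusted p = 1.17e-12, adjusted p = 0.0853 with an estimated correlation). Of 27 YAP, SRF and cytoskeleton genes 6 were higher over all genes, 12 adjusted over the list alone, and 15 higher and 2 lower in the paired test. Their median was 0.19 (camera adjusted p = 2.18e-06, adjusted p = 0.164 with an estimated correlation). Of 26 sarcomere genes Myom2 (2.33-fold), Csrp3 (1.83-fold) and Pdlim5 (1.52-fold) were higher, 4 adjusted over the list alone, and 8 were higher and 3 lower in the paired test. Their median was 0.13 (camera adjusted p = 0.000831, adjusted p = 0.673 with an estimated correlation), and 0.01 within well column 05 and 0.25 within column 07. Ace (1.90-fold), Nppb, Adra1a (1.55-fold) and the protease gene Furin (1.33-fold) were the 4 of 19 natriuretic and vasoactive genes that were higher, 5 adjusted over the list alone, and 6 were higher and 2 lower in the paired test. Their median was 0.11 (camera adjusted p = 0.00736, adjusted p = 0.0853 with an estimated correlation).

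Many division genes were lower with PE than with IGF1. Of 37 mitosis genes 21 were lower over all genes and 36 both adjusted over the list alone and in the paired test, with a median of -1.03 (camera adjusted p = 1.42e-26, adjusted p = 0.173 with an estimated correlation), the spindle motor genes Kif20a (2.34-fold lower) and Kif11 (2.25-fold lower) among those past the threshold. Of 35 DNA replication genes 25 were lower over all genes and 34 both adjusted over the list alone and in the paired test, including E2f1 (2.06-fold lower) and Pole (1.91-fold lower). Their median was -0.66 (camera adjusted p = 5.37e-33, adjusted p = 0.0853 with an estimated correlation). With PE against control 0 mitosis genes passed over all genes, adjusted over the list alone, in the paired test or at unadjusted p under 0.05 (limma, median -0.05). Of the DNA replication genes 0 passed with PE against control over all genes, adjusted over the list alone or in the paired test (limma, 1 higher at unadjusted p under 0.05). Their median there was 0.08 (camera adjusted p = 0.0143, paired 0.0199, adjusted p = 0.854 with an estimated correlation).

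A few metabolic and immune genes also differed between the agents. Of 19 cholesterol synthesis genes 0 passed over all genes or adjusted over the list alone (limma, 4 lower with PE at unadjusted p under 0.05) and 2 were lower in the paired test. Their median was -0.10 (camera adjusted p = 0.0462, adjusted p = 0.711 with an estimated correlation) and 0.01 within well column 07. Of 18 fatty acid synthesis genes 0 passed over all genes (limma, 7 lower at unadjusted p under 0.05), 4 were lower adjusted over the list alone and 11 in the paired test, with Fads1 foremost (1.46-fold lower, paired adjusted p = 0.00069, median -0.31, camera adjusted p = 0.000798, adjusted p = 0.266 with an estimated correlation). Hadh (1.79-fold lower) was the 1 of 29 fatty acid oxidation genes past the threshold, also adjusted over the list alone (5 lower in the paired test), and Aldoc (1.99-fold lower) the 1 of 23 glycolysis genes, 3 adjusted over the list alone (2 higher and 7 lower in the paired test). Of 33 complex I genes 0 passed over all genes or adjusted over the list alone (limma, 3 lower at unadjusted p under 0.05) and 10 were lower in the paired test. Their median was -0.15 (camera adjusted p = 0.00495, adjusted p = 0.745 with an estimated correlation) and -0.02 within well column 07. Of 31 FoxO target and insulin feedback genes Irs2 (1.96-fold), Igf1r (1.51-fold), Klhl24 and Insr (each 1.34-fold) were higher with PE and Sesn3 lower (1.72-fold), 10 higher and 1 lower adjusted over the list alone, 11 and 1 in the paired test. Their median was 0.16 (camera adjusted p = 9.06e-05, adjusted p = 0.173 with an estimated correlation). Of 30 inflammation genes Bdkrb2, Ccl20 (2.42-fold) and Il1rl1 (1.57-fold) were higher over all genes, 5 adjusted over the list alone, and 19 higher and 1 lower in the paired test. Their median was 0.45 (camera adjusted p = 3.83e-06, adjusted p = 0.541 with an estimated correlation). The 15 leukocyte markers moved the same way, with a median of 0.19, above 0 in 4 of 4 triplets, 0 higher over all genes (limma, 1 at unadjusted p under 0.05) and 2 in the paired test, and the 10 endothelial markers had a median of 0.13. Of 21 interferon response genes 0 passed over all genes or adjusted over the list alone (limma, 2 lower at unadjusted p under 0.05) and 14 were lower with PE in the paired test, including Mx2 (2.02-fold lower, paired adjusted p = 0.0157) and Usp18 (1.98-fold lower, 0.011). Their median was -0.42 (camera adjusted p = 0.00103, adjusted p = 0.687 with an estimated correlation). Of 41 matrix genes 4 were higher and 3 lower over all genes, 5 and 5 adjusted over the list alone, and 13 and 10 in the paired test, with the largest changes in Col3a1 (1.59-fold lower) and Eln (1.53-fold lower). Their median was 0.02 (camera adjusted p = 0.292). Of the 13 fibroblast markers Col3a1 was lower, also adjusted over the list alone, and 1 was higher and 5 lower in the paired test, with a median of -0.07 that was below 0 in 4 of 4 triplets.

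In the paired test 1299 genes were higher and 1608 lower with PE than with IGF1, among them all 651 of the unpaired test. Leaving out single arrays gave from 155 to 306 genes higher and from 158 to 372 lower, both lowest without PE replicate 3. Within well column 05, 44 were higher and 58 lower. Within column 07, with 1 PE array, 0 passed (limma, 698 higher and 831 lower at unadjusted p under 0.05), which with 1 residual degree of freedom says nothing about the other calls. The hypertrophy median was 0.57 and 0.63 and the mitosis median -0.814 and -1.002. In the tests of all 35 pathway lists, other splits of the same arrays, which part fewer triplets than the treatments do, passed as many lists, and with an estimated correlation 1 list passed in the paired test, so the lists are described through the tests of their genes.

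Genes changed by both agents were asked for because each is a hypertrophic stimulus. The steroid and isoprenoid enzyme genes Idi1 (log2 differences 0.96 with PE and 0.97 with IGF1) and Hsd17b7 (0.72 and 0.81), Eno3 (1.24 and 0.90), the tubulin gene Tubb4b (0.61 and 0.77) and the decoy receptor gene Tnfrsf22 (0.55 and 0.54) rose with both, among 15 genes. Fam107a (-0.76 and -0.66), Klf15 (-0.58 and -0.76), Chst9 (-0.59 and -0.54), Lpl (-0.64 and -0.41) and the glypican gene Gpc4 (-0.45 and -0.37) fell with both, among 6 genes. Chst9 lay at the lower quartile of the arrays with either agent, so its values are uncertain. Each of these 10 had the same direction in 4 of 4 triplets with either agent. Areg, an EGF receptor ligand gene (log2 differences 0.69 and -0.50), and Nt5e, the ecto-nucleotidase gene (0.67 and -0.58), were the 2 genes that rose with PE and fell with IGF1, and 0 did the reverse (limma), where the paired test gave 62 and 34.

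Both comparisons use the same 4 control arrays, which by itself produces shared changes. Independent lists of these sizes would share 1.76 genes higher and 0.214 lower. In 100 simulations of unchanged groups with shared controls 0 passed with both (limma), which says little because almost no gene passes in unchanged groups. With the controls split so that each agent had its own 2, the 6 arrangements gave 0 to 2 genes higher and 0 lower, where independent lists would share up to 0.151 and 0.023. Each agent then had 2 controls in place of 4, so fewer genes could pass with either. The paired test found 195 higher and 287 lower with both, and 39 to 51 and 42 to 84 with split controls, where independent lists would share 8.70 to 17.1 and 5.34 to 14.2. The correlation of the agents' log2 differences across genes was 0.316, and shared controls alone gave 0.478 in the simulations, where the groups were unchanged. With split controls it was -0.159 to 0.107 unpaired and 0.101 to 0.182 paired. The covariance was 0.0122, of which shared controls alone gave 0.00402 in the simulations, leaving 0.00815. With split controls it was -0.00934 to 0.0049 unpaired and 0.00466 to 0.0078 paired.

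**Figure D4:**
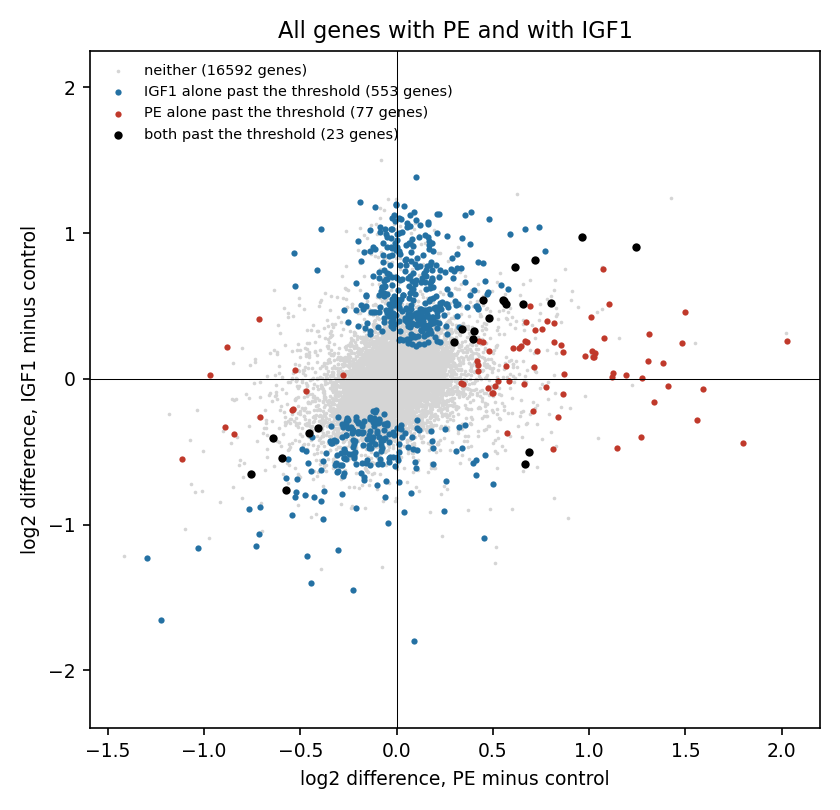
Log2 difference with PE (x axis) and with IGF1 (y axis) against the same 4 controls for 17245 genes, 1 point per gene. Of these, 77 passed the threshold with PE alone (red), 553 with IGF1 alone (blue), 23 with both (black) and 16592 with neither (grey).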

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

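Both tests of the inflammation genes with IGF1, and the test of the interferon genes without the triplet of the largest fall, were chosen only after the result was seen, and the others before it.

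Of 37 mitosis genes 16 were higher with IGF1 in the unpaired and 36 in the paired test, with a median log2 difference of 1.00 (camera with an estimated correlation, adjusted p = 0.178 and paired 0.105). A larger share of a whole cell type would raise its markers alike. Yet the median was 0.049 for 13 fibroblast markers (95% bootstrap interval -0.05 to 0.21), -0.13 for 10 endothelial markers (-0.20 to -0.11) and -0.27 for 15 leukocyte markers (-0.34 to -0.11). More dividing cells within a type could leave its markers flat, so these medians do not exclude that. Smooth muscle and epicardial markers were not compared this way. The most abundant markers were Vim and Dcn for fibroblasts (8732 and 6244 in controls, 8902 and 5518 with IGF1), Tek and Flt1 for endothelium (160.1 and 139.7, 146 and 126.7 with IGF1), and Fcer1g and Tyrobp for leukocytes (1144 and 949.1, 860.9 and 799.6 with IGF1), and 6 of the fibroblast markers stand on other lists. The rise was not seen in a single triplet alone, since the median was above 0 in every triplet, the smallest being 0.55 (0.43 to 0.69). All intervals given for this rise resample genes or markers, which vary together, and hold no spread between arrays. Cell cycle entry under IGF1 is a hypothesis for the rise that was not tested, as cell division was not measured. It leaves open which cells of the culture would be involved.

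Of 21 interferon response genes 8 were lower with PE in the paired test and 0 in the unpaired test (limma, 3 at unadjusted p under 0.05), with a median of -0.38 (camera with an estimated correlation, adjusted p = 0.854 and paired 0.273). Loss of leukocytes or endothelial cells as the whole cause would lower their markers alike. Their medians were smaller falls, at -0.061 (-0.15 to -0.01) and -0.083 (-0.10 to 0.06). For these markers and arrays this argues against either as the whole cause. The intervals resample markers and hold no spread between arrays. The brightest endothelial markers, Tek and Flt1, stood at only 160.1 and 139.7 in controls. Other cell types were not tested this way. The 9 epicardial markers had a median of -0.21, with 1 higher and 2 lower in the paired test. For the interferon genes the triplets were uneven, with medians from -0.025 (-0.10 to 0.09, which includes no change) to -0.63. Over the 3 triplets other than the last the median was -0.32 (-0.40 to -0.20), so the fall was not seen in that triplet alone. Whether it exceeds the spread between arrays cannot be told from this interval. Repression by PE may be part of it, a hypothesis that was not tested in another way.

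Of 30 inflammation and chemokine genes 18 were lower with IGF1 in the paired test and 0 in the unpaired test (limma, 4 at unadjusted p under 0.05), with a median of -0.40 (camera with an estimated correlation, adjusted p = 0.602 and paired 0.105). The 15 leukocyte markers had a median of -0.27, with 7 lower in the paired test and 0 in the unpaired test (limma, 1 at unadjusted p under 0.05). Their median fell less than that of the inflammation genes, by 0.12 (0.01 to 0.37). With a bound this near 0, and no spread between arrays in the interval, fewer leukocytes could explain part or all of the fall. The median of the inflammation genes was below 0 in every triplet, at -0.22 (-0.32 to -0.05) in the one closest to 0, so the fall was not seen in 1 triplet alone. That interval resamples genes and holds no spread between arrays either. A direct effect of IGF1 on these genes stays open beside a smaller share of leukocytes.

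Other splits of the 8 arrays of each comparison tested whether chance could give as many genes. With PE the 100 genes were matched by 1 of 35 splits, the real one, and the highest other split gave 1. With IGF1 the 576 genes were matched by 1 of 35, the highest other 0 (limma), and between the agents the 651 by 1 of 35, the highest other 0. Most of these splits put arrays of 1 triplet in the same group, so the spread between triplets enters their comparison. Only 8 splits part all 4 triplets as the real one does, too few for a share under 0.05. Among these the highest other was 0 in each comparison (limma), in the unpaired test and in the paired test, where the real split gave 1391, 2845 and 2907 genes. Of the pathway lists 12, 23 and 23 passed, and 22, 4 and 3 of 35 splits passed as many, the highest others being 22, 26 and 24, and the cause was not tested. Among the 8 splits that part all 4 triplets, too few here as well, the highest others were 10, 20 and 22. The 21 genes changed the same way by both agents were matched by 1 of 100 regroupings of the 12 arrays, the real one, with 0 as the highest other (limma). Of the 99 others 0 had a gene past the threshold with each agent, so no overlap could arise in them and they do not test it.

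A single array stood far from the other 3 of its group in 17 of 435 groups over 145 named genes. Chance would give 21.8 for independent groups. Many of these genes were picked by their values, and genes vary together, so 21.8 is only a rough guide. The count is not above it, but it cannot say whether a single flag is chance. The gap to the nearest array, as a share of the group's range, was 0.851 for Cavin4 in PE replicate 4 (41.84 against 83.59 to 94.3), 0.85 for Irf7 in PE replicate 1 (76.06 against 127.8 to 140.1), 0.917 for Gja1 in PE replicate 1 (3720 against 2503 to 2587) and 0.835 for Pamr1 in PE replicate 2 (75.89 against 98.53 to 103.7). With IGF1 it was 0.873 for Ccl20 in replicate 3 (104.4 against 135.8 to 141), 0.877 for Nppb in replicate 3 (6408 against 4327 to 4541), 0.962 for Cyp51 in replicate 4 (3179 against 3477 to 3490), 0.864 for Kif5a in replicate 4 (19.78 against 15.36 to 15.9), 0.859 for Ier5 in replicate 1 (148.4 against 135 to 136.8), 0.878 for Myh7 in replicate 1 (4625 against 5516 to 5653), 0.847 for Rgs2 in replicate 2 (243.2 against 157.7 to 168.5) and 0.83 for Scd2 in replicate 2 (4683 against 5238 to 5360). In controls it was 0.877 for Cxcl11 in replicate 3 (313.9 against 200.5 to 211.9), 0.956 for Map1lc3b in replicate 4 (1568 against 1448 to 1453), 0.904 for Rln3 in replicate 4 (12.75 against 15.92 to 16.3), 0.88 for Ube2t in replicate 2 (63.7 against 40.69 to 42.95) and 0.83 for Klhl24 in replicate 1 (1338 against 1139 to 1170).

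Probe sets left out for lack of a single symbol, 9608 with none and 962 with several, were tested among all 29214. That test called 54 probe sets of any kind with PE, 422 with IGF1 and 523 between the agents. The test over genes had called 100, 576 and 651. Of those with no symbol 6 passed with PE (5 higher and 1 lower), 55 with IGF1 (31 and 24) and 41 between the agents (27 and 14). Of those with several symbols 1 passed with PE (higher), 10 with IGF1 (3 and 7) and 17 between the agents (9 and 8).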

How the results depend on the processing

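Every alternative to the paired test, log2 with no pseudocount, leaving out arrays 1 to 3 and well column 07 alone were chosen after the data were seen. Counts are given in the order higher with PE, lower with PE, higher with IGF1, lower with IGF1, higher and lower with PE than with IGF1, and higher and lower with both agents, where the unpaired test gave 82, 18, 371, 205, 284, 367, 15 and 6. Kif5b stayed higher with PE and with IGF1 under every alternative, at log2 differences of 0.59 to 0.75 with PE and 0.17 to 0.33 with IGF1. Centring, quantile normalization and the mean over probe sets moved no unpaired count by more than 1.5 times and ended no call of Kif5b with PE.

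With the triplet block the counts were 672, 719, 1466, 1379, 1299, 1608, 195 and 287. The triplets take up 50.7% of the variance, which the block removes from the error. Fitting only the 2 groups compared, with fewer arrays for the error, gave 15, 5, 149, 100, 183, 227, 2 and 1. An adjusted p threshold of 0.01, stricter by construction, gave 8, 3, 48, 35, 113, 93, 1 and 0 (limma, 368 for the last at unadjusted p under 0.05). The fold limit of 1.5, also stricter, gave 10 lower with PE, 172 and 54 with IGF1, 133 and 197 between the agents, and 4 and 1 with both. Leaving out the dimmest genes gave 28 lower with PE. Array weights gave 55 lower with PE, 309 lower with IGF1, 436 higher with PE than with IGF1 and 23 lower with both. The trend with robust priors gave 12 lower with both, and no pseudocount gave 3. Without arrays 1 to 3, 34 were lower with PE and 224 higher with IGF1. For array weights, the level filter, the trend, the pseudocount and arrays 1 to 3 the cause was not tested.

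With the well column as a block 125 were higher and 52 lower with PE, and 12 lower with both, and the cause was not tested. Within well column 05, with 8 arrays, the counts were 0, 0, 43, 8, 44, 58, 0 and 0 (limma, 613, 528, 146 and 141 in place of the zeros at unadjusted p under 0.05). Well column 07 holds 1 control, 1 PE and 2 IGF1 arrays, which leaves 1 residual degree of freedom and takes the lone arrays to vary like the IGF1 ones. All 8 counts were 0 there (limma, 387, 718, 420, 724, 698, 831, 70 and 256 at unadjusted p under 0.05), in a test too small to say whether a call depends on the column.

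Leaving out 1 array gave 11 to 80 genes higher with PE. The count was 49 without Control replicate 1, 41 without IGF1 replicate 1, 32 without Control replicate 2, 17 without PE replicate 2, 15 without Control replicate 3, 11 without PE replicate 3, 48 without IGF1 replicate 4 and 30 without Control replicate 4. Genes lower with PE numbered 3 to 41, with 9 without IGF1 replicate 1, 41 without PE replicate 1, 3 without Control replicate 2, PE replicate 2 or Control replicate 3, 10 without IGF1 replicate 3, 4 without PE replicate 3 and 11 without PE replicate 4. Genes higher with IGF1 numbered 84 to 396, with 166 without Control replicate 1, 195 without IGF1 replicate 1, 84 without Control replicate 3, 92 without IGF1 replicate 3, 207 without IGF1 replicate 4 and 143 without Control replicate 4. Genes lower with IGF1 numbered 50 to 201, with 125, 50 and 110 without Control replicates 1, 3 and 4, 111, 120, 61 and 109 without IGF1 replicates 1 to 4, and 135 without PE replicate 4. Between the agents 155 to 306 were higher with PE, with 155 without PE replicate 3 and 169 without IGF1 replicate 4, and 158 to 372 lower, with 181 and 225 without IGF1 replicates 3 and 4 and 158 and 207 without PE replicates 3 and 4. Higher with both were 2 to 16, with 8, 8, 3 and 8 without Control replicates 1 to 4, 6, 9, 6 and 9 without IGF1 replicates 1 to 4, and 6 and 2 without PE replicates 2 and 3. Lower with both were 0 to 13, with 2, 3, 2 and 3 without IGF1 replicates 1 to 4, 13 and 3 without PE replicates 1 and 4, and 0 without Control replicate 2, Control replicate 3, PE replicate 2 or PE replicate 3 (limma, 353, 291, 262 and 295 at unadjusted p under 0.05). Fewer arrays explain a lower count in part, and why single arrays differed was not tested.

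The call of Kif5b with PE ended with only the 2 groups compared (log2 difference 0.67, adjusted p = 0.0536), at the threshold of 0.01 (0.67, adjusted p = 0.0143) and within well column 05 (0.69, adjusted p = 0.213). Column 07, too small for a test, gave 0.59 (adjusted p = 0.662). Across the alternatives to the unpaired test its adjusted p ran from 0.000508 to 0.662. Without single arrays the difference was 0.60 to 0.75, and the call ended without Control replicate 3 (0.65, adjusted p = 0.0588) and without PE replicate 3 (0.60, adjusted p = 0.0546). In the paired test it passed under every alternative, at 0.60 to 0.72 without single arrays. With IGF1, Kif5b passed with the triplet block (0.26, adjusted p = 0.0304) and was 0.22 to 0.31 without single arrays in the unpaired test. The paired call ended with quantile normalization (0.23, adjusted p = 0.0609), the fold limit (0.26), the threshold of 0.01 (0.26) and without arrays 1 to 3 (0.24, adjusted p = 0.124). Without single arrays it was 0.20 to 0.31, and the call ended without Control replicates 1, 2 and 3 (0.24, 0.27 and 0.20) and IGF1 replicates 1 to 4 (0.26, 0.25, 0.24 and 0.28).

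In the paired test the fold limit gave 160, 92, 279, 156, 250, 330, 19 and 24 in the same order, and the threshold of 0.01 gave 317, 246, 779, 631, 744, 852, 58 and 86. Only the 2 groups compared gave 450 lower with PE and 184 lower with both. Without arrays 1 to 3, 974 were higher with IGF1, and 127 higher and 185 lower with both. Without single arrays the ranges were 379 to 681, 337 to 705, 1018 to 1425, 935 to 1359, 937 to 1287, 1105 to 1614, 114 to 193 and 150 to 274. Genes higher with PE fell to 443 and 379 without PE replicates 2 and 3, and genes lower with PE to 380 and 416 without Control replicates 2 and 3 and 338 and 337 without PE replicates 2 and 3. Genes higher with both numbered 115, 114, 127, 128 and 119 without Control replicates 1 and 3, IGF1 replicate 1, PE replicate 2 and PE replicate 3. Genes lower with both numbered 191, 150, 160, 156 and 156 without IGF1 replicate 1, Control replicates 2 and 3, and PE replicates 2 and 3.

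Of the 35 pathway lists, 12, 23 and 23 passed in the 3 comparisons, and 0, 0 and 1 with an estimated correlation. That correlation ran from -0.023 (natriuretic and vasoactive genes) to 0.862 (interferon response), where the preset value was 0.01. It was 0.854 for mitosis and 0.458 for DNA replication. For lists whose genes vary together this much, camera p-values with the preset correlation are likely too small. Without single arrays 11 to 15, 15 to 25 and 18 to 26 passed, the 15 for IGF1 without IGF1 replicate 2. The interferon list with IGF1, with a median of 0.00 and not called, turned to -0.25 (adjusted p = 0.0205) without Control replicate 1, and the cause was not tested. Some medians shrank by over 1.5 times within a well column, and the cause was not tested. With PE these included fatty acid oxidation (-0.12 in column 05) and cardiomyocyte markers (0.11 in column 07). With IGF1 in column 07 they included fatty acid synthesis (0.29), glycolysis (0.06), tRNA synthetases (0.11), immediate early genes (-0.04), inflammation (-0.22), and leukocyte (-0.05), endothelial (-0.07) and epicardial markers (-0.05), and in column 05 amino acid response (0.15). Between the agents they included in column 07 fatty acid synthesis (-0.15), adult-type genes (-0.04), inflammation (0.185), and leukocyte (0.08) and endothelial markers (0.002), and in column 05 interferon response (-0.16). Without arrays 1 to 3 the immediate early median with IGF1 was -0.105. Of 327 other differences of named genes, 0 that were called in the unpaired test or under the alternative turned around (limma). Changes of sign in differences called in neither were not counted. With the triplet block 97 gained a call and 0 of the 160 called lost theirs, while 133 lost theirs within well column 05, 113 at the threshold of 0.01, 79 with only the 2 groups compared, 48 without arrays 1 to 3, 42 with the fold limit and 13 with the well column as a block. Without 1 array 31 (PE replicate 1) to 90 (Control replicate 3) lost theirs, and 106 of the 160 did so without at least 1 array. In column 07, too small for a test, 160 did. In controls Chst9 and Kif5a (each 17.0), Rln3 (15.2), Ercc6l (18.6) and Kif5c (24.5), and with PE Chst9 (10.9), lie at or not far above the lower quartile of the arrays' intensities, 10.73 to 11.49, where background limits how far a fold can be read.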

Other observations

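Tests of the lists named here were planned, and Scn4b, Kcnj3, Kcnj2 and Gja1 were picked after their values were seen. Of 40 ion channel and calcium handling genes 11 fell and 5 rose with PE in the paired test. In the unpaired test 0 passed over all genes or adjusted over the list alone (limma, 6 lower and 3 higher at unadjusted p under 0.05). Camera called no direction for the list (adjusted p = 0.346, paired 0.17). Among those that fell in the paired test were the sodium channel subunit gene Scn4b (1.80-fold lower, paired adjusted p = 0.0107), the inward rectifier genes Kcnj3 (1.66-fold lower, 0.000667) and Kcnj2 (1.39-fold lower, 0.00588), and Gja1, of the main ventricular gap junction protein (1.31-fold lower, 0.00853), each lower in 4 of 4 triplets. The list's median was -0.06.

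With IGF1, ribosome biogenesis genes had a median of 0.10 over 37 genes (camera adjusted p = 0.00173, adjusted p = 0.467 with an estimated correlation), with 0 past the threshold over all genes or adjusted over the list alone (limma, 6 higher at unadjusted p under 0.05) and 3 in the paired test. Their median was 0.03 without arrays 1 to 3 and 0.02 within well column 07. The 30 ribosomal protein genes had a median of -0.10 (camera adjusted p = 0.00413, adjusted p = 0.589 with an estimated correlation), with 0 past the threshold over all genes, adjusted over the list alone or at unadjusted p under 0.05 (limma), and 1 lower in the paired test.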
